A study of Mus musculus with 2 samples.

How the data were processed

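The series holds 2 single-cell RNA libraries of CD8+ T cells sorted from MC38 tumours, a mouse colon carcinoma line grown in mice, collected 9 days after implantation. One library came from control mice and the other from mice depleted of natural killer (NK) cells with an antibody against NK1.1. Per the labels' protocols, tumours were minced and digested with collagenase, live CD8+ cells were sorted by flow cytometry, and libraries were made with the 10x Genomics 5' chemistry. The control library carries the treatment label PBS, while its library name carries the abbreviation Iso; the labels do not say which injection the control mice had. The number of mice behind each library is not given in the sources used here.

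The files hold UMI counts per gene and barcode, whole numbers that were not normalized, as deposited by the authors. The counts were made with Cell Ranger 6.1.2, per the file headers, and the submitters' processing notes name the mm10 genome build and Seurat 4.0.6. The deposited matrices hold 7866 control barcodes and 10111 NK-depleted barcodes over 32285 genes. They sum to 108106687 and 128853437 UMIs. Every barcode has at least 500 UMIs. The matrices carry no cell annotation.

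Cells were kept with at least 500 detected genes and a mitochondrial share of UMIs under 10%. Scrublet, run in scanpy 1.11.5 on each library alone with an expected doublet rate of 0.08, called only 1 doublet per library. This is too few for a caller that worked, so doublets must be taken as largely unremoved. Values without the 8% of cells with the highest doublet scores are given in the closing section. The filters kept 7162 control and 8352 NK-depleted cells.

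Both libraries were clustered together without integration. Counts per 10000 were log-transformed after adding 1, and 2000 variable genes were chosen. T cell receptor and immunoglobulin segments, mitochondrial, ribosomal protein and sex-linked genes were left out of that choice. Clustering used 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0, on numpy 2.4.6 and scipy 1.17.1. A cluster entered the CD8 T population if at least 50% of its cells had a UMI of Cd3d, Cd3e or Cd3g, at least 50% had one of Cd8a or Cd8b1, and markers of another cell type did not name it. Marker lists were fixed before the data were examined. The thresholds for using them were set afterwards. Another cell type needed 3 markers at 4-fold over the remaining cells, with 1 among the 10 leading genes, and a T cell state needed 3 markers at 2-fold, taking the state with the largest fraction of its markers raised and no name on a tie. A cluster counted as cycling with 2 cycling markers at 2-fold. A further later rule gave no state name to a cluster led by Ly49 receptor or other NK cell genes. It also gave none to a cluster of few UMIs whose leading genes held no marker of the state. A Ly49-led cluster and a cluster of few UMIs stayed unnamed. The Ly49-led cluster had 4 of 8 gamma delta T cell markers at 4-fold, but none among its 10 leading genes, so it stayed in the population. It had 4 of 8 progenitor exhausted markers at 2-fold, the largest fraction of any state, and only the further rule left it without that name. Cluster 9 had 5 of 9 naive or central memory markers and 5 of 9 circulating effector markers at 2-fold, a tie, and is outside the naive-like share. The Ly49-led and few-UMI clusters held 3.87% and 1.69% of control CD8 T cells, and 6.91% and 2.46% of NK-depleted CD8 T cells.

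Counts were summed over the CD8 T population of each library and expressed as CPM, the count of a gene over all counts of that library's population. Each ratio is NK-depleted over control, with an exact conditional binomial 95% interval, and shares carry exact Clopper-Pearson 95% intervals. These intervals cover counting error only. With 1 library per group there is no replicate spread. No test was run and no p-value is given, and the number of genes past a size threshold describes these libraries only. Genes of at least 50 CPM in 1 library were counted at a ratio of 1.5 or more in either direction. For 21 gene lists, the median log2 ratio was taken over members of at least 10 CPM, and its percentile was found among 10000 random lists of equal size matched on mean expression. Members that differed by at least 1.25-fold were counted.

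Shares of cells with a UMI of a gene were compared after thinning each cell to 5400 UMIs. That depth is the lower of the libraries' 10th percentiles, rounded down. This left out 614 control and 794 NK-depleted cells. The named genes follow a rule written before the data were examined. It took the 12 largest and 12 smallest ratios that kept their direction under each scaling, leaving out receptor segments, mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed genes. It added up to 4 members per list with the largest difference, and a fixed set of CD8 T cell genes. The result for 1 of these genes is not reported here. Coordinates are 1-based from the GENCODE vM21 annotation, whose build is the one the submitters name, matched on Ensembl gene identifier. All 116 named genes were found. Reads shared by near-identical genes were assigned or discarded upstream in a way not checked here, so the granzyme cluster, the Ifit, Ifitm and Ly49 families carry that uncertainty.

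The ratio, list and count steps were tested on simulated sums for this comparison, drawn over 2860 genes of at least 50 CPM with 200 genes changed. The draws followed the counting model that the intervals assume, without variation between libraries and with each gene drawn independently. They therefore check the calculation and not the spread of real libraries. The intervals covered the known ratio for 94.8% of genes. All genes changed 2-fold were counted past the 1.5-fold threshold (100%), against 0% of those changed 1.25-fold, and 0 unchanged genes were counted. A list of 20 genes raised 1.25-fold fell at the 100th percentile, while 4 of 100 unchanged lists fell outside the central 95%.

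Alternatives were stricter and absent cell filters, doublet calls kept, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, means over cells, other definitions of the population, thinned sums, other count minimums, other thinning depths and other clusterings. Added after seeing the data were the removal of high doublet scores, the removal of the Ly49-led and few-UMI clusters, and clustering without genes that differed 1.5-fold between libraries. The bootstrap over members used as the spread of a list median, and the share of 85% of a cluster's cells that marks it as mostly 1 library, were also set after seeing the data.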

Results

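The study asked how NK cells bear on the differentiation of CD8+ T cells inside a tumour. It compared 1 library of CD8+ T cells from MC38 tumours of control mice with 1 library from mice depleted of NK cells. After filtering, the control library held 7162 cells with a median of 11165.5 UMIs and the NK-depleted library 8352 cells with a median of 12081 UMIs. The CD8 T population made up 6803 control cells (94.99% of cells kept, 102647186 UMIs) and 8137 NK-depleted cells (97.4%, 122747493 UMIs). There are no replicates, so no difference below can be set against a spread between animals, and intervals cover counting error only.

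The labels could be checked only in part, since the sort removes NK cells. Over all barcodes, Ncr1, which encodes the NK cell receptor NKp46, had 33 UMIs in the control library and 11 in the NK-depleted library, a ratio of 0.280 (0.128 to 0.567). Over the CD8 T population it had 27 and 3 UMIs. Cd8a stood at 887 and 696 CPM, Cd8b1 at 1141 and 869 CPM, and Cd3e at 648 and 550 CPM in the control and NK-depleted libraries. Most markers of other cells were scarce within the population. The fibroblast markers reached at most 1.27 CPM (Col1a2), the erythroid markers 0.0779 CPM (Alas2), the dendritic cell markers 6.71 CPM (Cd74), the macrophage markers 11.9 CPM (Cd68) and the CD4 T cell markers 23.3 CPM (Ikzf4). The highest members of the lists for endothelial cells (Pecam1, 20.7 CPM), tumour epithelium (Cdh1, 17.0 CPM), neutrophils (Il1r2, 25.03 CPM), gamma delta T cells (Trgv2, 20.6 CPM), B cells (Ighm, 52.1 CPM) and NK cells (Fcer1g, 59.9 CPM) are genes that T cells can carry. Summed over the list, gamma delta T cell markers stood at 32.5 and 54.2 CPM and NK cell markers at 68.9 and 108.76 CPM in the control and NK-depleted libraries, and Trdc, the delta chain constant region, at 2.16 and 5.50 CPM. Gamma delta T cells in the population were thus not excluded. The median mitochondrial share of UMIs in CD8 T cells was 2.26% in the control library and 2.81% in the NK-depleted library.

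CD8 T cells kill tumour cells with granzymes and perforin released from granules. Under lasting antigen they lose function and take on inhibitory receptors, a course that the factor Tox supports. Interferons, from NK cells, T cells and others, switch on a shared set of response genes in the cells they reach. Across the CD8 T population, the NK-depleted library had more transcript of the granzymes C to F, of cell division genes and of glycolytic enzymes. It had less of interferon-response genes, of the chemokine Ccl5, of the transcription factor Tox and of the integrin Itga4. Of 3019 genes with at least 50 CPM, 20 were at least 1.5-fold higher in the NK-depleted library and 77 were at least 1.5-fold lower. The higher genes were 20.6% of these. With TMM factors the numbers were 35 and 48 (42.2% higher) and with median-of-ratios factors 36 and 47 (43.4% higher), so the balance between higher and lower genes depended on the scaling. Most genes (81.9%) differed by less than the smaller fold used below to count list members.

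Granzymes, the proteases of cytotoxic granules, led the genes that were higher. Gzmf (chromosome 14, 56205263 to 56211417, minus strand, protein coding) stood at 382 CPM in the control library and 1557 CPM in the NK-depleted library, a ratio of 4.08 (4.04 to 4.12). Gzmc (chromosome 14, 56231441 to 56234656) was 4.06-fold higher (3.98 to 4.14), from 106 to 432 CPM. Gzmd stood at 45.0 and 128 CPM and Gzme at 36.4 and 86.1 CPM. Gzmb, the main granzyme of effector cells, differed less, at 2142 and 2829 CPM, and the pore-forming Prf1 stood at 355 and 412 CPM. Gzmk went the other way, at 89.8 CPM in the control and 34.5 CPM in the NK-depleted library. Over the 15 measured members of the cytotoxic granule list, 6 were higher past the fold set for list members and 2 lower, and the median log2 ratio was 0.05 (percentile 88.1 of random lists, bootstrap interval over members -0.16 to 0.48). The other genes with the largest ratios were the interferon-induced membrane proteins Ifitm2 (174 and 556 CPM), Ifitm1 (480 and 937 CPM) and Ifitm3 (266 and 504 CPM), the metallothionein Mt1 (53.5 and 148 CPM), the cell cycle inhibitor Cdkn1a (28.8 and 61.8 CPM), Fcer1g (30.3 and 59.9 CPM), Myo10 (27.5 and 52.6 CPM) and the stress-induced Ddit4 (40.0 and 70.8 CPM). The Fcer1g difference depended on the population, with a log2 ratio of 0.98 here and 0.39 over all kept cells, and Fcer1g was lower in 4 of 12 clusters.

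**Figure D1:**
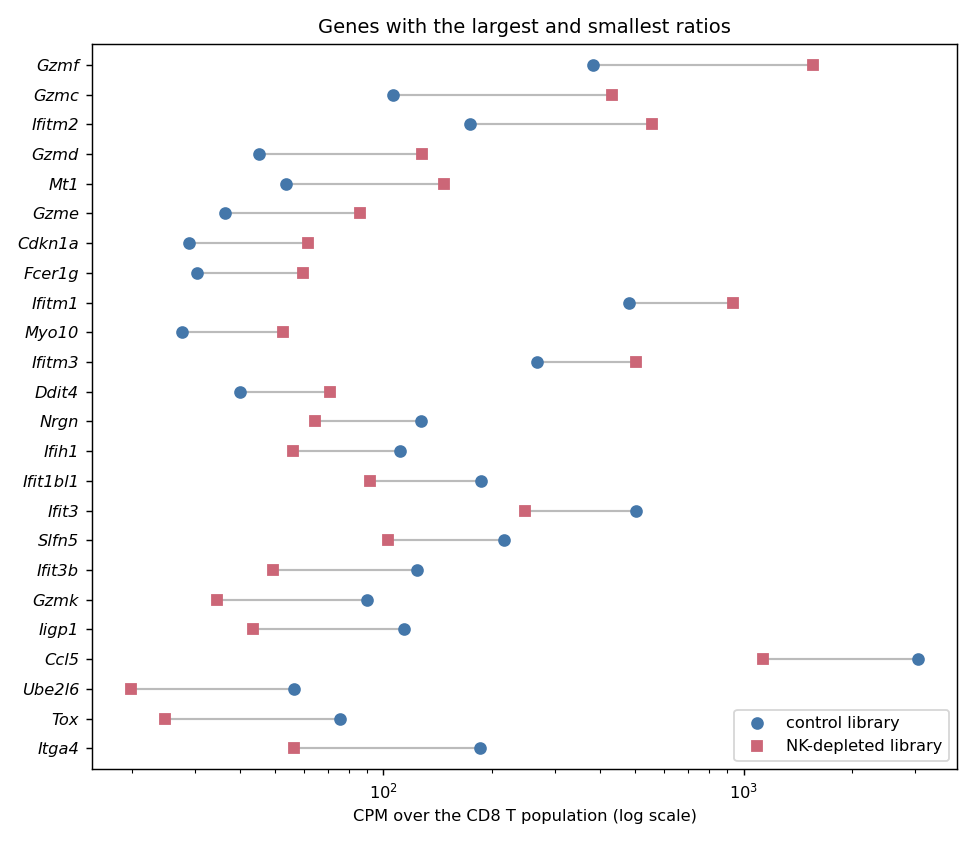
CPM over the CD8 T population (log axis) of the 12 genes with the largest and the 12 with the smallest ratios, with circles for the control library and squares for the NK-depleted library. Gzmf lies at 382 CPM in the control library and 1557 CPM in the NK-depleted library, and Itga4 at 185 and 56.4 CPM.

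Interferon-response genes were lower in the NK-depleted library. Of the 19 measured members of the type I interferon list, 17 were lower and 0 higher, with a median log2 ratio of -0.53, below all random lists (percentile 0). Ifit3 stood at 504 CPM in the control library and 247 CPM in the NK-depleted library, 2.04-fold lower (2.01 to 2.07). Ifit1 stood at 357 and 188 CPM, Ifit2 at 188 and 97.4 CPM, and Oas1a at 52.4 and 27.9 CPM. Isg15 stood at 754 and 490 CPM, while Usp18 did not follow the list, at 154 and 163 CPM. On the interferon gamma list, 12 of 20 members were lower and 0 higher (median -0.36, percentile 0), led by the GTPase genes Iigp1 (114 and 43.3 CPM), Gbp2 (130 and 77.5 CPM) and Gbp5 (55.8 and 33.8 CPM). Ifit3b, Ifit1bl1, Slfn5, Ifih1 and Ube2l6, which are also induced by interferon, were among the smallest ratios. The Ifitm genes named above are interferon-inducible too and had the opposite direction.

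Among the remaining smallest ratios, Itga4 (chromosome 2, 79255426 to 79333123, the alpha 4 integrin subunit used for adhesion to VCAM-1) stood at 185 CPM in the control library and 56.4 CPM in the NK-depleted library, 3.28-fold lower (3.19 to 3.37). Tox (chromosome 4, 6686353 to 6991557), a factor needed for the exhausted state, stood at 75.5 and 24.7 CPM, 3.06-fold lower (2.94 to 3.19). Ccl5 stood at 3053 and 1132 CPM and the signalling gene Nrgn at 127 and 64.6 CPM. On the cytokine and chemokine list, 5 of 9 measured members were lower and 1 higher (median -0.43, percentile 0), although the bootstrap interval over members, -0.65 to 0.18, included 0. Its lower members included Ccl3 (271 and 163 CPM), Ccl4 (903 and 575 CPM) and Ifng (440 and 326 CPM), whereas Tnf stood at 15.6 and 16.6 CPM. Il2 stood at 5.57 and 8.27 CPM.

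The list of inhibitory receptors and exhaustion had a lower median in the NK-depleted library, with members in both directions. Of 12 measured members, 6 were lower and 2 higher, and the median log2 ratio was -0.33 (percentile 0.01, bootstrap interval over members -0.68 to 0.07). Beside Tox, the lower members were Nr4a2 (156 and 89.8 CPM), Cd38 (41.0 and 24.3 CPM), Lag3 (427 and 283 CPM), Ctla4 (222 and 155 CPM) and Cd101 (18.3 and 13.8 CPM). The inhibitory receptor Havcr2 stood at 135 and 140 CPM, Entpd1 at 67.3 and 71.3 CPM, and Pdcd1, which encodes PD-1, at 215 and 179 CPM. Tigit was under the list's minimum, at 7.67 and 4.79 CPM. Cd244a and Lilrb4a were the higher members.

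The stem and memory list showed no shared direction. Of its 14 measured members, 3 were higher, 3 lower and 8 between, with a median log2 ratio of -0.10 (percentile 28.4). Slamf6, a marker of progenitor cells, stood at 38.01 CPM in the control library and 20.7 CPM in the NK-depleted library, and Cd27 at 185 and 133 CPM. Tnfsf8 (14.6 and 28.1 CPM) and Bcl2 (272 and 360 CPM) were higher. Tcf7 stood at 63.3 and 55.2 CPM and Il7r at 259 and 265 CPM. The median turned positive when cycling clusters were left out (0.09), with means over cells (0.07), with a minimum of 50 CPM (0.04) and, near 0, with thinned counts (0.00).

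Genes of the cell cycle were higher in the NK-depleted library. On the G2 and M phase list, 23 of 26 members were higher and 0 lower, with a median log2 ratio of 0.42 (percentile 100). Mki67 stood at 273 and 373 CPM, Top2a at 281 and 438 CPM, and the mitotic kinase genes Plk1 at 21.6 and 31.9 CPM and Ttk at 7.95 and 12.9 CPM. On the S phase list, 13 of 24 members were higher and 0 lower (median 0.36, percentile 100), among them Cdc6, Uhrf1, Mcm5 and Mcm7. Without the cycling clusters, the S phase median was 0.06, with 2 of 20 measured members higher, and the G2 and M phase median 0.20, with only 8 members measured, 3 higher and 1 lower. Glycolysis and hypoxia genes were also higher, with 7 of 19 members higher and 0 lower (median 0.27, percentile 100). Bnip3 stood at 19.4 and 39.2 CPM, Tpi1 at 240 and 355 CPM, Pgk1 at 326 and 450 CPM and Aldoa at 623 and 848 CPM. Oxidative phosphorylation genes had a median of 0.07 (percentile 96.9), with 0 of 21 members higher and 1, Ndufa4, lower.

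**Figure D2:**
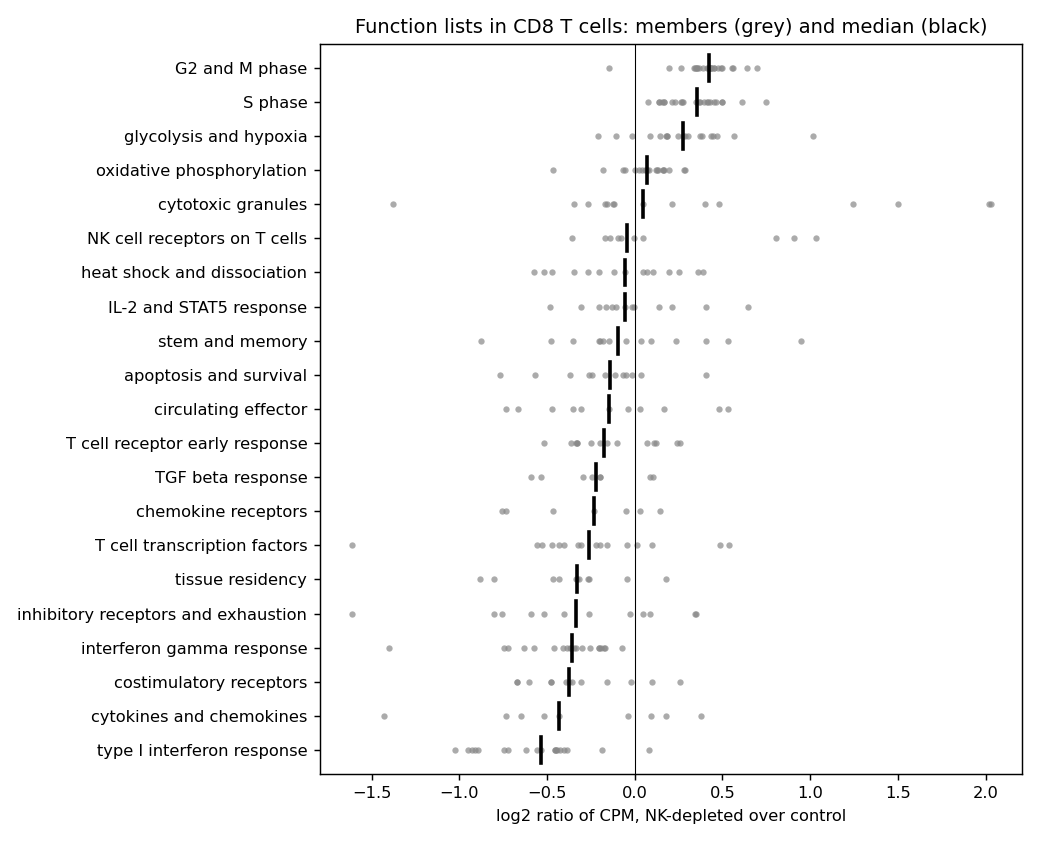
Log2 ratio of CPM, NK-depleted over control, for each measured member (grey) and the median (black) of the 21 function lists over the CD8 T population. The type I interferon list has the lowest median, -0.53, and the G2 and M phase list the highest, 0.42.

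The remaining lists were lower or undirected. Costimulatory receptors were lower in 8 of 13 members and higher in 0 (median -0.38, percentile 0), with Slamf1 (41.0 and 25.8 CPM), Cd7 (47.3 and 29.7 CPM), Tnfrsf1b (91.8 and 60.6 CPM) and Cd28 (252 and 181 CPM) the furthest. Tissue residency genes were lower in 6 of 11 members and higher in 0 (median -0.33, percentile 0.02), with the residency chemokine receptor Cxcr6 at 442 and 319 CPM. Itgae was under the minimum, at 8.26 and 2.12 CPM. T cell transcription factors had 7 of 16 members lower and 2 higher (median -0.26, percentile 0.09). Nfatc1 (115 and 79.7 CPM) and Ikzf3 (114 and 77.2 CPM) were lower, and Ikzf2 (122 and 177 CPM) and Eomes (21.0 and 29.3 CPM) higher, while Tbx21 stood at 64.3 and 51.9 CPM. Chemokine receptors (median -0.23, percentile 3.58) included Cxcr3 (79.7 and 47.1 CPM) and Cx3cr1 (63.8 and 38.3 CPM). TGF beta response genes (median -0.22, percentile 2.97) included Pmepa1 (192 and 127 CPM) and Tgif1 (44.8 and 30.9 CPM). Early T cell receptor response genes had a median of -0.18 (percentile 4.15), with Rel at 98.9 and 69.1 CPM and Nr4a1 at 55.4 and 43.1 CPM. The bootstrap intervals over members included 0 for the chemokine receptor (-0.74 to 0.03), TGF beta (-0.45 to 0.09) and early T cell receptor response (-0.33 to 0.10) lists.

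The other lists lay within the range that random lists often reach. Circulating effector genes had a median of -0.15 (percentile 12.4), with Gzma at 229 and 320 CPM and Klf3 at 33.3 and 21.0 CPM, and Klrg1 was low, at 3.05 and 4.79 CPM. Apoptosis and survival genes had a median of -0.14 (percentile 13.0), with Bcl2a1d at 294 and 173 CPM and Mcl1 at 322 and 250 CPM. The bootstrap interval over members of that list, -0.32 to -0.03, excluded 0. Its median was also below 0 in 12 of 12 clusters with at least 100 cells in each library, from -0.37 to -0.01. The heat shock and dissociation list had a median of -0.06 (percentile 39.5), in which Fosb (87.6 and 58.7 CPM) and Junb (723 and 520 CPM) were lower and Hsp90aa1 (342 and 448 CPM) higher. The IL-2 and STAT5 list had a median of -0.06 (percentile 43.2), with Il2ra, the high-affinity IL-2 receptor chain, at 72.9 and 114 CPM and Socs3 at 51.7 and 36.9 CPM. NK cell receptors on T cells had a median of -0.04 (percentile 52.0), although the Ly49 genes Klra6, Klra3 and Klra7 were higher, the last at 17.9 and 31.2 CPM. Under TMM and median-of-ratios factors the medians of the last 3 of these lists turned positive, by at most 0.04.

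Shares of positive cells were compared at 5400 UMIs per cell. Cells with a UMI of Mki67 or Top2a made up 36.2% (35.0 to 37.5) of control cells and 51.1% (49.9 to 52.2) of NK-depleted cells, a difference of 14.8 percentage points. In the naive-like cluster, where few cells should divide, the shares were 9.07% and 20.5%, so the background differed in the same direction. The dendritic-like clusters stood at 23.7% (16.8 to 31.8) and 36.8% (27.2 to 47.4). Cells with Slamf6 and without Havcr2 made up 14.6% (13.8 to 15.5) of control and 8.14% (7.53 to 8.79) of NK-depleted cells. In the naive-like cluster they made up 30.1% and 26.8%. Cells with Havcr2 made up 28.2% (27.1 to 29.4) and 33.2% (32.2 to 34.3), against 0.490% and 4.23% in the naive-like cluster. This background rose in the same direction and Havcr2 CPM was near level, at 135 and 140, so a part of the Havcr2 difference may be background. Stray Havcr2 UMIs would also lower the share with Slamf6 and without Havcr2. In dendritic-like cells the Slamf6 share was 13.3% and 11.6%, and the Havcr2 share 24.4% and 34.7%, so those clusters, which also held T cell transcripts, set no lower floor. Without thinning the same 3 shares were 49.4% and 64.0%, 19.7% and 11.2%, and 38.3% and 47.2%. Cells with Pdcd1 made up 52.5% (51.3 to 53.8) of control and 44.8% (43.7 to 46.0) of NK-depleted cells, against 4.41% and 6.18% in the naive-like cluster. In the dendritic-like clusters the Pdcd1 share was 39.3% (31.0 to 48.0) and 34.7% (25.3 to 45.2). Cells with Gzmb made up 83.7% and 91.2%, but naive-like cells, which should lack Gzmb, reached 30.6% and 65.4%, so this difference was not read as expression. Tcf7 was seen in 20.3% and 21.2% of cells. Its CPM had the opposite order, and no order was read from the share. Klrg1 was seen in 1.07% (0.826 to 1.35) and 1.59% (1.32 to 1.91) of cells, against 0 of 408 naive-like control cells (0 to 0.900%) and 0.325% of naive-like NK-depleted cells. Median depths of the naive-like cluster were 10238 and 9028 UMIs, those of the dendritic-like clusters 19162 and 18957 UMIs, and those of the CD8 T population 11303 and 12145 UMIs.

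The CD8 T population fell into 14 clusters. The cycling clusters (3, 4, 10 and 11), led by histone, Mcm and mitotic genes, held 17.8% of control and 30.5% of NK-depleted CD8 T cells. Each held more of the NK-depleted library. Cluster 4 (5.10% and 9.77%), led by Mcm genes, had only 2 of 12 cycling markers raised 2-fold and no name, and cluster 11 (2.43% and 4.34%) also raised 5 of 8 gamma delta T cell markers. Cluster 0, named terminally exhausted-like from 5 of 12 markers and led by Csf1, Tnfrsf4, Lag3, Rgs16 and Havcr2, held 18.9% (18.0 to 19.9) and 16.3% (15.5 to 17.1). Cluster 5, naive or central memory-like and led by Il6ra, Igfbp4 and S1pr1, held 6.22% (5.66 to 6.82) and 8.20% (7.61 to 8.81). These differences depended on the clustering, from -9.67 to -1.28 points for the terminally exhausted-like share and from 0.168 to 2.30 points for the naive-like share, so only the direction of the former was read and no difference in the naive-like share. A pair of clusters lay mostly in 1 library each. Cluster 2, led by Actn2, Car2, Gzmk, Itga4 and Ccl5, was named interferon responsive-like from 8 of 9 markers raised. It held 22.0% (21.0 to 23.0) of control and 1.08% (0.868 to 1.33) of NK-depleted CD8 T cells. Its median mitochondrial share (1.18%) and UMIs (7977) were below those of the control CD8 T population. Cluster 1, unnamed and led by Tnfsf8, Lilrb4a, Ms4a4c, Bcl2 and Ccr2, held 3.22% (2.81 to 3.67) and 23.1% (22.2 to 24.0). With 1 library per group, such a cluster may be the library and not a cell type. Both are led in part by genes that differed between the libraries. When genes that differed 1.5-fold were left out of the clustering, the cluster holding most cells of cluster 2 took 26.6% of control and 1.61% of NK-depleted cells. The one holding most cells of cluster 1 took 3.07% and 19.4%.

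**Figure D3:**
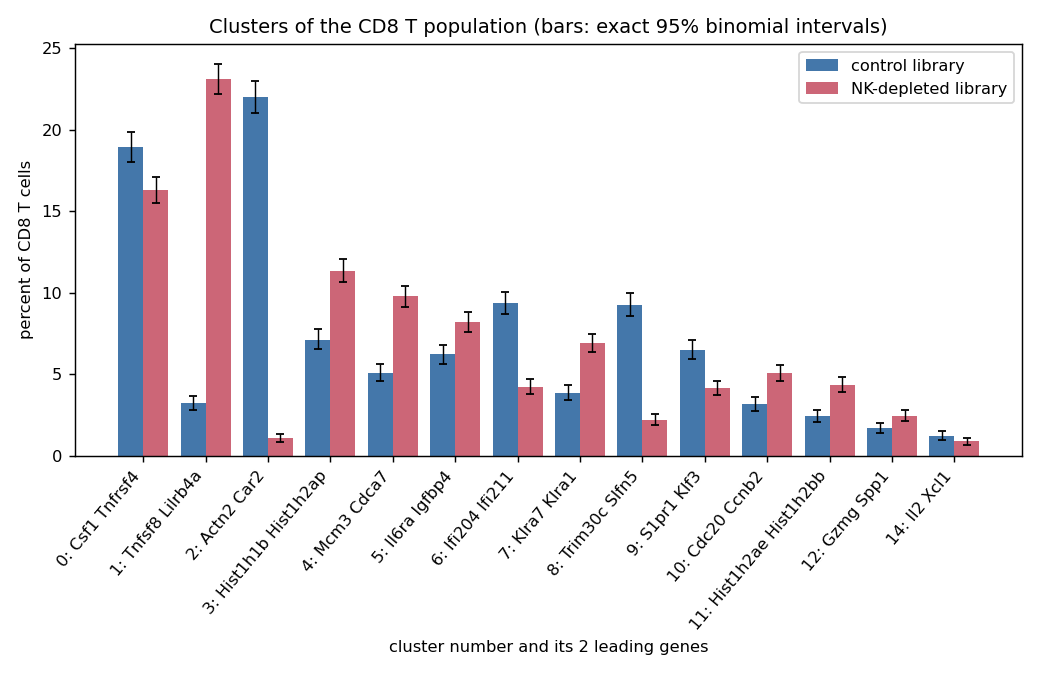
Share of CD8 T cells in each cluster in the control and NK-depleted libraries, in percent, with exact 95% binomial intervals as error bars. Cluster 2 holds 22.0% of the control and 1.08% of the NK-depleted library, and cluster 1 holds 3.22% and 23.1%.

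Of the smaller clusters, cluster 6 (Ifi204, Slfn5, Csf1) held 9.35% of control and 4.22% of NK-depleted CD8 T cells. Cluster 8 (Trim30c, Slfn5, Rsad2, interferon responsive-like) held 9.26% and 2.20%, and cluster 9 (S1pr1, Klf3, Klf2) 6.51% and 4.15%. The Ly49-led cluster 7 held 3.87% and 6.91%, the few-UMI cluster 12 held 1.69% and 2.46%, and the early activated-like cluster 14 (Il2, Xcl1, Ccl4) held 1.21% and 0.873%. Clusters 6 and 8 are defined by interferon genes that themselves differed between the libraries, so their sizes are not a separate result. Outside the CD8 T population lay a macrophage or monocyte-like cluster (202 and 100 cells), a pair of dendritic cell-like clusters (140 and 100 cells together) and an unnamed cluster led by Shisal2b and Rhox5 (17 and 15 cells).

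Within clusters of at least 100 cells in each library, of which there were 12, several differences recurred. Ifit3 was lower in the NK-depleted library in 12 of 12 clusters. Tox was lower in 12 as well, but within counting error in the naive-like and few-UMI clusters, and Itga4 in 11, being level in cluster 9 (374 and 372 CPM). Slamf6 was lower in 11, within counting error in clusters 5, 6, 9 and 12. Gzmf was higher in 11 of 12 clusters, the exception being the few-UMI cluster 12, whose leading genes include Gzmg, Gzmd, Gzmc and Gzme. Gzmc and Gzmd were each lower in 1 of 12 clusters and Gzme in 1 of 11, at log2 ratios of -2.11, -0.84 and -0.49. In naive-like cells Gzmf stood at 8.45 and 87.2 CPM, which was taken as free RNA. Clusters 7, 8, 9 and 11 had similarly little Gzmf, up to 13.1 CPM in the control and 197 CPM in the NK-depleted library. The Gzmf difference was thus read only in clusters 0, 1, 3, 4, 6 and 10, among them the terminally exhausted-like cluster 0, at 556 and 3460 CPM. The glycolysis list had a median above 0 in 12 of 12 clusters, from 0.13 to 0.57. The type I interferon list was below 0 in 10 of 12 clusters. It was lowest in the few-UMI cluster 12, at -1.01, followed by cluster 9, at -0.87. It was not lower in the terminally exhausted-like cluster, at 0.08, or in the Ly49-led cluster 7, at 0.05. The list of inhibitory receptors and exhaustion was below 0 in 9 of 12 clusters, with -0.18 in the terminally exhausted-like cluster, and highest in the naive-like cluster, at 0.48 over 7 members, which was not read as expression given the Havcr2 background there. The cytotoxic granule list was above 0 in 8 clusters and below 0 in 4. Its highest median, 0.37, lay in cluster 9, where the Gzmf difference was not read, so the count may hold free RNA. The stem and memory list was below 0 in 8 clusters, down to -0.40 in cluster 7, but at 0.50, 0.59, 0.63 and 0.78 in clusters 6, 8, 11 and 12. The G2 and M phase list was -0.08 over the cycling clusters together, where Mki67 stood at 761 and 745 CPM.

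**Figure D4:**
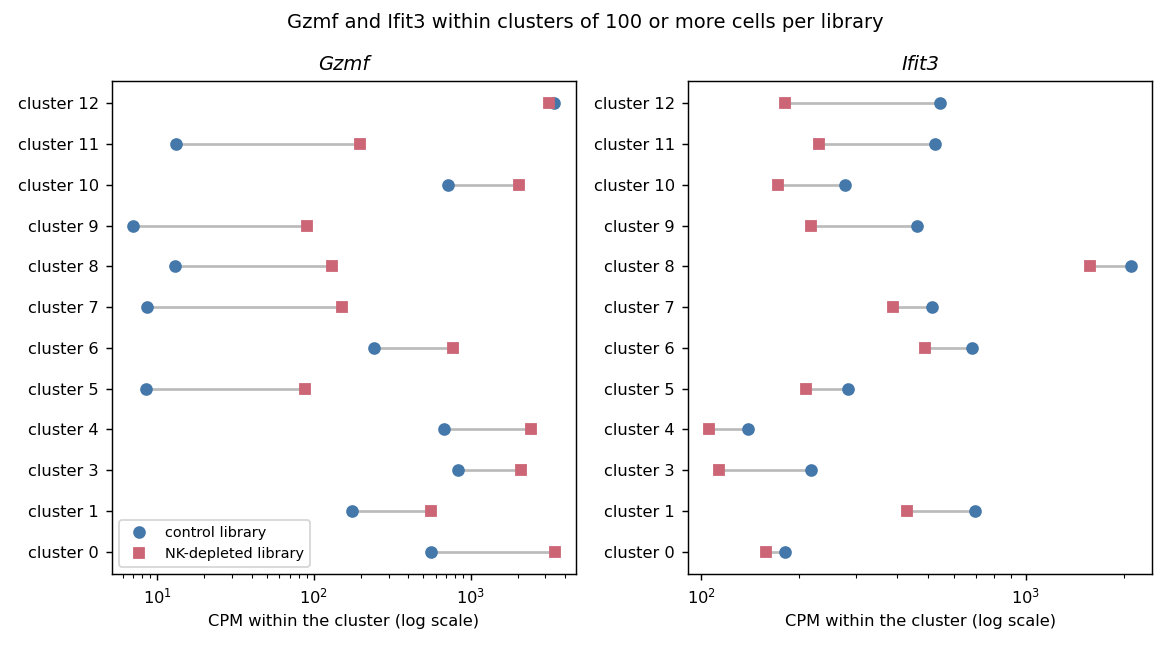
CPM of Gzmf (left) and Ifit3 (right) within each cluster with at least 100 cells in both libraries (log axes), with circles for the control library and squares for the NK-depleted library. Ifit3 is lower in the NK-depleted library in 12 of 12 clusters. Gzmf is higher in 11 of 12, with the naive-like cluster at 8.45 and 87.2 CPM.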

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

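The tests of cycling cells and of free RNA for the granzymes, and of a shift in gene means for the clusters, were chosen after the values they rest on had been seen in part. The other tests in this part were written first.

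Data that the comparisons left out also differed between the libraries. Barcodes with a mitochondrial share of at least 10% made up 13.0% (12.3 to 13.7) of the NK-depleted and 5.89% (5.38 to 6.43) of the control library, and barcodes under 500 genes made up 8.90% and 6.28%. T cell receptor beta segments were left out of the gene comparison. Among the 2739 NK-depleted and 2623 control cells with 1 leading Trbv segment, Trbv2 led in 12.2% and 7.93%, Trbv13-2 in 7.996% and 4.65%, Trbv20 in 5.04% and 2.97%, and Trbv1 in 4.64% and 2.10%. Other segments went the other way, with Trbv12-1 in 2.85% and 5.45%, Trbv29 in 3.36% and 6.37%, and Trbv13-1 in 9.02% and 13.6%.

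Interferon-response genes were lower in the NK-depleted library, and neither of the explanations tested, a change in the mix of states and a difference in RNA quality, was excluded. A change in the mix of states would leave these genes level within a state. The highest of the 3 medians examined was 0.0821, in the terminally exhausted-like cluster, while the naive-like cluster stood at -0.16 and the cycling clusters at -0.33. This result fell between the bounds set for either reading, and the clusters were built partly from these genes. The interferon responsive-like clusters 2 and 8 held 22.0% and 9.26% of control CD8 T cells. In the NK-depleted library they held 1.08% and 2.20%. Over the 12 clusters with at least 100 cells in each library, the median was at or below -0.2 in 8 and above 0 in 2. A difference in RNA quality was tested in 4 equal groups of cells ordered by mitochondrial share. The medians ran from -0.55 to -0.25, so the difference remained below 0 in each group but did not reach the bound of -0.4 in all of them, and it may account for a part. The depletion of NK cells, the mice and the preparation stay open.

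Granzymes C, D, E and F were higher in the NK-depleted library. More cycling cells do not account for this as the whole cause, because over the clusters that do not cycle the median log2 ratio of the 4 genes was 1.97. Free RNA accounts for at most a small part. Naive-like cells showed between 6.70% and 7.44% of the population's CPM difference, a near-constant fraction over the 4 genes. Such a fraction is far from the whole. Free RNA could leave it, but so could unremoved doublets, so its constancy does not tell these apart. In relative terms the gap in naive-like cells was wider, with Gzmf at 8.45 and 87.2 CPM against 382 and 1557 CPM over the population. NK depletion is a candidate explanation that these data did not test, as is a difference between the mice. A change in the mix of states that do not cycle was not tested either.

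Clusters 1 and 2 each lay mostly in 1 library. Expanded clones were tested by Trbv segment alone. The commonest segment led in 18.1% (14.7 to 21.8) of cells with 1 leading segment in cluster 2 of the control library. In cluster 1 of the NK-depleted library it led in 12.4%. These shares argue against 1 dominant clone as the whole cause. A few clones with different segments could give the same shares, so they stay open. Only 481 of 1495 control cells of cluster 2 had 1 leading segment. The commonest segment of cluster 2 was Trbv29. Over the control population, cluster 2 included, it led in 6.37% of such cells, and over the NK-depleted population in 3.36%. Because cluster 2 is part of the control figure, that comparison understates its excess. Expansion could therefore account for a part of that cluster. A shift in the mean of each gene is argued against as the whole cause. With genes scaled within each library the matching clusters still differed by 7.45-fold and 8.84-fold in share. The match was made on leading genes from unscaled counts. For cluster 2 these include Gzmk, Itga4 and Ccl5, which differed between the libraries. The match thus favours a skewed cluster, and the size of the folds may be overstated. Mice, sort and library preparation, to which the low mitochondrial share of cluster 2 (median 1.18%) could belong, cannot be told apart from NK depletion, because there is 1 library per group.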

How the results depend on the processing

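None of the values examined reversed a called direction. Across the alternatives, the type I interferon median ran from -0.69 to -0.45, the inhibitory receptor median from -0.35 to -0.25 and the cytotoxic granule median from 0.02 to 0.17. Spread for a list median was its bootstrap interval over members, and for a share or named gene its counting interval. Of 294 list values, 280 kept their sign and 15 moved beyond the spread. Of 70 values for shares of positive cells, 69 kept their sign and 12 moved. For shares of states, 10 of 17 values moved and none changed sign. The number of higher genes was 35 with TMM, 36 with median of ratios, 31 with thinned counts, 89 at 10 CPM, 9 at 200 CPM, 8 at 2-fold and 1515 with no count minimum. The number of lower genes was 48, 47, 103, 217, 20, 10 and 2356 for the same settings. Means over cells gave 30 higher and 100 lower. The fewer or greater number of genes under another minimum or fold follows from the construction, and for the scalings the cause was not tested. The G2 and M phase median was 0.20 without cycling clusters, 0.45 without the Ly49-led and few-UMI clusters, 0.50 with TMM, with median of ratios, with means over cells and with thinned counts. The share with Slamf6 and without Havcr2 differed by -8.51 points without thinning, -3.44 at 0.5 times the depth and -7.79 at the 25th percentile of depth. The Havcr2 share differed by 6.77 points with no cell filter, 6.76 in UMI-gated cells, 8.11 without the Ly49-led and few-UMI clusters and 8.89 without thinning. The Mki67 or Top2a share differed by 13.1 points under the stricter filter. The Pdcd1 share differed by -4.81 points at 0.5 times the depth, the Klrg1 share by 0.239 under the stricter filter and 1.11 without thinning, the Tcf7 share by 2.54 without thinning and the Gzmb share by 6.21 at 0.5 times the depth. The terminally exhausted-like share differed by -7.45 points at resolution 0.5, -5.89 at 1.5, -5.23 with genes scaled within each library, -9.67 without cell cycle genes and -1.28 without genes differing 1.5-fold. The naive-like share differed by 0.17 points at resolution 1.5, 1.14 with scaled genes and 0.98 without differing genes, and no cluster had that name at resolution 0.5. The cycling share differed by 9.19 points with scaled genes and 7.28 without cell cycle genes. The cause of these shifts was not tested. Without the 8% of cells with the highest doublet scores, 21 genes were higher and 79 lower, the G2 and M phase median was 0.41 and the type I interferon median -0.53, and the differences were -6.35 points for Slamf6 without Havcr2, 6.30 for Havcr2 and 14.4 for Mki67 or Top2a. Removal of high doublet scores or of the Ly49-led and few-UMI clusters, and clustering without differing genes, were chosen after seeing the data. Of 1392 values for named genes, 1389 kept their sign and 559 moved beyond counting error. The count of kept signs was partly fixed in advance. The 12 largest and 12 smallest ratios were chosen for keeping their direction under TMM, median-of-ratios and cell-mean scaling. List members were chosen for a large difference. No paired analysis was possible because each group has 1 library.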

Other observations

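The test in this part was chosen after its values had been seen. The cluster led by Ly49 receptor genes (Klra7, Klra1, Klra6, Klra9, Klra3) and Ikzf2 is a population that the comparisons by state did not name. Markers of other cells were raised there, with 5 of 8 gamma delta T cell markers and 3 of 9 NK cell markers at 2-fold over the remaining cells, so it was not shown to be purely CD8 alpha beta T cells. The cycling cluster 11 also had 5 of 8 gamma delta T cell markers at 2-fold. In the Ly49-led cluster, Gzmb stood at 606 CPM in the control and 1526 CPM in the NK-depleted library, a ratio of 2.52 (2.39 to 2.65). Naive-like cells, a guide to free RNA, stood at 220 and 320 CPM of Gzmb, a smaller difference in the same direction. The share of naive-like cells with a Gzmb UMI after thinning differed more, at 30.6% in the control and 65.4% in the NK-depleted library. The CPM and the shares thus give different sizes for the background. Background of unknown size therefore lies within the Gzmb difference of the Ly49-led cluster. Xcl1 went the other way, at 543 and 376 CPM. The Ly49 genes that lead it ran from 1.37-fold lower (Klra9) to 1.205-fold higher (Klra3) there, and Fcer1g stood at 326 CPM in both.

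Klrb1c encodes NK1.1, the target of the depleting antibody, so the antibody could also remove CD8 T cells that carry it. Over the CD8 T population Klrb1c was not lower but higher in the NK-depleted library, at 3.83 and 5.25 CPM, a ratio of 1.37 (1.21 to 1.56). This ratio pools clusters whose shares differed between the libraries, so it cannot decide on removal. Cluster 1 held 102 of the 371 NK-depleted cells with a Klrb1c UMI, against 11 of 185 such control cells. In the Ly49-led cluster, which had the largest share of Klrb1c-positive cells in the control library, it was lower, at 47.8 CPM in the control and 18.1 CPM in the NK-depleted library, 2.64-fold lower (2.05 to 3.39). There 21.3% (16.5 to 26.7) of 263 control cells and 12.5% (9.84 to 15.5) of 562 NK-depleted cells had a UMI. Klrb1c was lower in 4 of 10 clusters with counts in both libraries, and in cluster 9 the share with a UMI was 5.19% (3.32 to 7.69) and 2.07% (0.837 to 4.22). Removal of some of these cells, or lower transcript per cell, therefore remains open. The rule for this test was widened after the Ly49-led cluster was seen to go the other way, and its outcome is that the tables cannot tell.

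Interferon-inducible genes did not move as a single group. Ifitm1, Ifitm2 and Ifitm3, neighbours on chromosome 7, were 1.95-fold, 3.19-fold and 1.89-fold higher in the NK-depleted library, while the Ifit genes on chromosome 19 were lower. Among cells with 1 leading Trbv segment the effective number of segments was 13.5 in the control and 13.98 in the NK-depleted library.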
